A study of Pseudomonas putida KT2440 with 6 samples.

How the data were processed

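Libraries of RNA from Pseudomonas putida KT2440, a soil bacterium that takes up glucose through its periplasm and catabolises it by the Entner-Doudoroff pathway, were compared between cells grown on glucose and cells grown on myristic acid, a saturated long-chain fatty acid. Per the labels, cultures started from overnight growth in minimal medium with glucose, were diluted to an optical density of 0.1 in minimal medium with either 0.5% glucose or 0.25% myristic acid, were shaken at 30 degrees Celsius and were collected at an optical density of 0.8. Groups and replicate numbers were taken from the sample titles, which gave 3 libraries per group and 6 in all. The labels do not say that each library came from its own culture, so the p-values measure only the spread between these libraries, which may be technical.

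The expression table that the authors deposited gives FPKM, fragments scaled to transcript length and library size, for each entry in each library, per the file headers. Per the submitters' processing notes, the authors used TopHat, Bowtie, Cufflinks and edgeR; their versions, the genome build and whether counting used strand are not given in the sources used here. The FPKM table held 4634 entries with 5506 gene names. Of these entries, 637 joined more than 1 gene, so that a value of such an entry belongs to all of its genes, and 288 shared their whole span with another entry. Another 128 entries were listed at 0 in every library, and 237 entries were shorter than 200 bases. A comparison table from the authors holds log2 fold changes and p-values of the same contrast for 4583 of these entries, per the file headers, and the deposited fold changes are on the log2 scale. That p-value is reported with an adjusted value, the false discovery rate, in the authors' table, and both are used here only beside the values computed from FPKM.

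The files gave no read counts, so no count model was fitted here. The relative depth of the libraries was estimated from the steps between low FPKM values, over 574 entries with a single gene, no overlap and low values. With the deepest library, myristic acid replicate 3, set to 1, the relative depth was 0.684, 0.869 and 0.848 for glucose replicates 1 to 3 and 0.839 and 0.878 for myristic acid replicates 1 and 2. Over 18 entries of 400 to 700 bases, 1 fragment was worth a median of 0.754 to 1.10 FPKM, depending on the library. Values of a few FPKM therefore rest on few fragments.

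FPKM values were used as deposited. Entries with a mean FPKM of at least 1 over the 6 libraries, 4405 in all, were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, a mean-variance trend and no replicate block, and p-values were two-sided and adjusted by the Benjamini-Hochberg method over all entries tested. An entry was called at an adjusted p below 0.05, and a second count asked also for an absolute log2 fold change of at least 1. Fold changes are myristic acid minus glucose on the log2(FPKM + 1) scale, which understates the change of entries with low values. The error of a fold change is its moderated standard error (SE), and the error of a mean FPKM is the standard deviation (SD). Simulated data on 4405 entries had 200 changed. There the procedure recovered 54% of the changes of 1 log2 unit and 92% of those of 2 log2 units. It made 8 false calls among 154. The simulated noise was independent and normal with the fitted variances. These rates may differ in the real data, where some entries share their span and more entries were called.

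Before the data were examined, 33 gene lists were written down from memory by locus tag or symbol. The main test, the alternatives and the rule for the genes named were also set then. Of 227 genes given by locus tag, 1 was not matched and 1 was dropped because the name in the file contradicted it. The genes were matched to entries through the names in the expression table. Where a name there differed from the listed one, the place between neighbouring locus tags decided. For NADH dehydrogenase I, ATP synthase and alginate, genes were also taken by symbol from the names in the expression table at this step. The gene pckA was not matched and is not analysed here. The reference table of names, for assembly LBNL_KT2440_1968, matched 804 of the 1387 names that are not locus tags, and its coordinates were not used. Lists with at least 3 tested entries, 32 in all, were tested with camera in limma at a preset correlation of 0.01, and again with an estimated correlation and with fry, with Benjamini-Hochberg adjustment over the lists. With an estimated correlation, camera uses only the 4 residual degrees of freedom, which by itself raises p. For each list the number of called members was also taken with p-values adjusted over the list alone.

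The genes named are the 10 with the largest rise and the 10 with the largest fall among called entries with a mean FPKM of at least 10 in the higher group and no overlap between the libraries of each group, up to 4 members per list with the lowest adjusted p, any member of a list of up to 5, and a fixed set of genes of fatty acid, storage polymer and glucose metabolism and their regulators. Coordinates are those of the authors' table on the single chromosome, counted from 1; the build is not given in the sources used here. Alternatives were other pseudocounts, other filters on low values, 2 other scalings, limma without a trend or with robust moderation, a replicate block and each library left out in turn. One further alternative, without entries shorter than 200 bases, entries that share their span and RNA entries, was added after seeing the data. The alternatives with DESeq2 and with a count model had been listed for the case that counts were found and did not apply. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.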

Results

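The transcriptome of Pseudomonas putida KT2440 was measured by RNA sequencing in 3 libraries of cells grown on glucose and 3 libraries of cells grown on myristic acid, all collected at the same optical density. The question was which genes differ in expression when a long-chain fatty acid replaces glucose as the only carbon source. Read totals were not analysed here; the relative depth of the libraries ranged from 0.684 in glucose replicate 1 to 1 in myristic acid replicate 3. On log2(FPKM + 1), the correlation across genes lay between 0.949 and 0.960 for pairs of glucose libraries, between 0.954 and 0.962 for pairs of myristic acid libraries, and between 0.896 and 0.919 for pairs from different groups. Genes are not independent replicates, so these values only describe the libraries.

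On myristic acid, both genes of the glyoxylate shunt and most, but not all, tested entries for fatty acid beta-oxidation and polyhydroxyalkanoate storage rose, while the genes for glucose uptake, periplasmic glucose oxidation and the Entner-Doudoroff pathway fell, most of them to a small fraction of their level on glucose. On the log2(FPKM + 1) scale, the largest rise was that of aceA, which encodes isocitrate lyase, from 57.9 ± 3.39 FPKM on glucose to 11475 ± 644 FPKM on myristic acid (SD, n = 3 each). On the same scale, the largest fall was that of PP_1015, which encodes the sugar-binding protein of the glucose ABC transporter (gtsA), from 2861 ± 627 to 12.3 ± 1.65 FPKM. By the ratio of mean FPKM, PP_3384, listed as a subunit of gluconate dehydrogenase, fell more (277-fold, against 233-fold for PP_1015). The genes of ATP synthase rose by a smaller and more even amount, and those of the pyruvate dehydrogenase complex fell.

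By limma, 917 of 4405 entries differed between the groups, 510 higher and 407 lower on myristic acid. With an absolute log2 fold change of at least 1, 348 entries remained, 185 higher and 163 lower. The excess of higher entries depended on the scaling: with median-of-ratios scaling 455 entries were higher and 454 lower, or 176 and 176 at least 1 log2 unit apart. With quantile normalization the counts were 515 and 433, or 188 and 168. The count of 917 fell to 553, 366 and 426 without myristic acid replicate 1, 2 and 3. Among the lower entries, the count of 407 fell to 266 and 269 without glucose replicates 1 and 2, and to 270, 159 and 181 without myristic acid replicates 1, 2 and 3. Among the higher entries, the count of 510 fell to 283, 207 and 245 without myristic acid replicates 1, 2 and 3. Of the entries at least 1 log2 unit apart, the 185 higher ones fell to 123 without myristic acid replicate 3 and the 163 lower ones to 108 without myristic acid replicate 2.

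**Figure D1:**
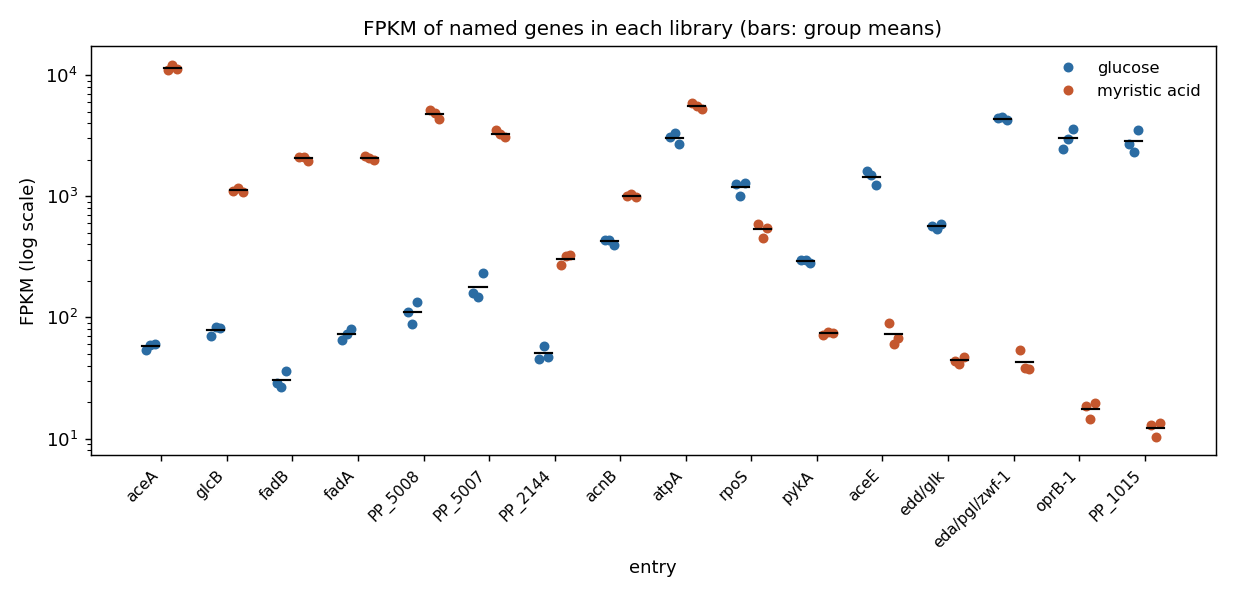
FPKM on a log axis for 16 named entries in each of the 3 glucose and 3 myristic acid libraries, with the mean of each group as a black bar. Examples range from aceA at 57.9 and 11475 FPKM on average to PP_1015 at 2861 and 12.3 FPKM.

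Both genes of the glyoxylate shunt, the bypass that lets cells build sugars from acetyl-CoA, rose. The log2 fold change was 7.61 ± 0.09 (SE) for aceA (4653520 to 4654845; limma adjusted p = 8.8e-08) and 3.82 ± 0.10 for glcB, encoding malate synthase (433021 to 435198; adjusted p = 9.9e-07). The short entry PP_4117, which starts shortly after the end of aceA, was also among the 10 largest rises, with 69.9 ± 21.5 FPKM on glucose and 2841 ± 175 FPKM on myristic acid; at 183 bases it is shorter than most entries, and its FPKM is less certain. The list has 2 members and was not given a set test.

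Of 27 tested entries for fatty acid uptake, activation and beta-oxidation, 16 rose, 1 fell and 10 were not called, and 19 rose and 1 fell when adjusted over the list alone. The list stood higher than other entries by camera (median log2 fold change 1.64, adjusted p = 4.82e-12), with adjusted p = 0.112 with an estimated correlation. With a pseudocount of 10 the median was 0.86. The genes fadB and fadA, encoding both subunits of the fatty acid oxidation complex, rose from 30.6 ± 5.11 to 2053 ± 77.7 FPKM and from 72.3 ± 7.78 to 2071 ± 92.6 FPKM, with log2 fold changes of 6.03 ± 0.13 and 4.83 ± 0.11. Among the 10 largest rises were also PP_3754, listed as a beta-ketothiolase (6.41 ± 0.18), its neighbours paaH (6.09 ± 0.16) and PP_3756 (5.96 ± 0.36), and PP_0370, an acyl-CoA dehydrogenase (5.32 ± 0.11). PP_0368, also an acyl-CoA dehydrogenase, rose by 4.20 ± 0.10. The acyl-CoA synthetase gene fadD rose from 245 ± 30.2 to 1752 ± 70.0 FPKM, a log2 fold change of 2.84 ± 0.11 (adjusted p = 7.2e-06). The neighbouring synthetase gene fadD2 had 37.0 ± 10.8 and 54.9 ± 5.84 FPKM (0.59 ± 0.22, adjusted p = 0.104) and was not called. Without glucose replicate 3 it was (adjusted p = 0.0429). PP_1893, listed as fadE, was low in both groups, with 3.90 ± 0.728 and 3.74 ± 1.04 FPKM, and was not called (adjusted p = 0.888). The single member that fell was the entry joining PP_2708 and PP_2709, listed for an acyl-CoA synthetase, chosen after its values were seen, from 41.4 ± 8.76 to 3.55 ± 0.964 FPKM. PP_2144, listed as psrA, a regulator that responds to fatty acids, rose from 50.5 ± 7.07 to 306 ± 31.3 FPKM, a log2 fold change of 2.58 ± 0.14 (adjusted p = 3.65e-05).

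Of 9 tested entries for polyhydroxyalkanoates, the polyesters that this bacterium stores as granules, 7 rose, 1 fell and 1 was not called, and 8 rose and 1 fell when adjusted over the list alone. The list was higher by camera (median 2.16, adjusted p = 3.38e-07; adjusted p = 0.0533 with an estimated correlation). The granule-associated protein genes rose most. PP_5008, listed as phaI, rose from 111 ± 22.9 to 4805 ± 411 FPKM (5.45 ± 0.16). PP_5007, listed as phaF, rose from 180 ± 45.6 to 3285 ± 214 FPKM (4.21 ± 0.18). PP_4817, listed as a hydratase gene that links beta-oxidation to polymer synthesis, rose by 4.08 ± 0.15. The entry named phaA in the file, at the place of the polymerase gene phaC1, rose by 2.16 ± 0.12 and the depolymerase entry PP_5004, listed as phaZ, by 2.30 ± 0.12. The gene phaG, encoding an enzyme that links fatty acid synthesis to the polymer, fell by 1.07 on the log2 scale with an SE of 0.22, from 59.4 ± 16.8 to 26.9 ± 0.311 FPKM (adjusted p = 0.0195). The call of phaG held without glucose replicate 3 (adjusted p = 0.0029) and ended without glucose replicate 1 (0.0612) or 2 (0.057) and without myristic acid replicate 1 (0.0609), 2 (0.0811) or 3 (0.0706).

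All 10 tested entries for glucose uptake and the Entner-Doudoroff pathway fell, also when adjusted over the list alone (median log2 fold change -6.55). The list was lower by camera (adjusted p = 7.56e-17), with adjusted p = 0.0902 at its estimated correlation of 0.36. The glucose ABC transporter entries PP_1015 (-7.74 ± 0.18), PP_1016/PP_1017 (-7.49 ± 0.16) and PP_1018 (-7.48 ± 0.14) lie side by side with the porin gene oprB-1 (-7.33 ± 0.17), from position 1157866 to 1163574. The entry joining eda, pgl and zwf-1 fell from 4368 ± 119 to 43.1 ± 9.05 FPKM (-6.65 ± 0.15), and gap-1, a glyceraldehyde-3-phosphate dehydrogenase gene, from 1629 ± 128 to 17.7 ± 1.07 FPKM (-6.44 ± 0.10). The entry joining edd and glk fell less, from 564 ± 25.7 to 44.3 ± 2.91 FPKM (-3.64 ± 0.10). The regulator gene hexR, chosen after its values were seen, fell from 121 ± 37.5 to 40.2 ± 2.28 FPKM, but it shares its listed span with PP_1020, so its FPKM is uncertain.

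All 11 tested entries for periplasmic glucose oxidation and for the uptake and use of gluconate and 2-ketogluconate fell, also when adjusted over the list alone (median -6.60, camera adjusted p = 3.65e-16; adjusted p = 0.0533 with an estimated correlation). PP_3384, PP_3383 and PP_3382, listed as the subunits of gluconate dehydrogenase, fell from 785 ± 65.7, 705 ± 67.8 and 375 ± 3.57 FPKM to 2.83 ± 0.337, 5.08 ± 0.579 and 1.93 ± 0.502 FPKM. The entry joining PP_3418 and the gluconate transporter gene gntP changed by -7.36 ± 0.12, PP_3377, listed as a 2-ketogluconate transporter, by -6.96 ± 0.19, kguD by -6.46 ± 0.25 and gnuK by -5.58 ± 0.41. The glucose dehydrogenase gene gcd, whose enzyme starts the periplasmic route, was low on both carbon sources and moved least, from 10.4 ± 1.29 to 6.13 ± 0.799 FPKM (-0.68 ± 0.19, adjusted p = 0.0444). Its call did not hold when any library was left out, with adjusted p of 0.0672, 0.116 and 0.0808 without glucose replicates 1, 2 and 3 and of 0.109, 0.126 and 0.0732 without myristic acid replicates 1, 2 and 3.

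Of 4 tested entries for pyruvate kinase and pyruvate dehydrogenase, 3 fell and 1 was not called, with the same counts when adjusted over the list alone (median -2.95, camera adjusted p = 0.00062; adjusted p = 0.112 with an estimated correlation). The genes aceE and aceF fell from 1442 ± 196 to 72.4 ± 14.8 FPKM and from 427 ± 35.0 to 27.4 ± 5.79 FPKM, and pykA from 293 ± 10.2 to 74.1 ± 1.82 FPKM. The entry with pykF had 5.94 ± 2.05 and 7.15 ± 1.28 FPKM. The tricarboxylic acid cycle did not move one way: of 19 tested entries, 5 rose, 4 fell and 10 were not called, or 6 and 7 when adjusted over the list alone (median -0.18 and lower by camera, adjusted p = 0.847; higher by fry). Aconitase gene acnB rose by 1.25 ± 0.09 and sdhA of succinate dehydrogenase by 0.67 ± 0.09. The isocitrate dehydrogenase gene PP_4012 fell from 619 ± 84.1 to 209 ± 14.1 FPKM (-1.55 ± 0.13), and the entry of succinyl-CoA synthetase genes sucC and sucD from 11105 ± 868 to 6245 ± 325 FPKM (-0.83 ± 0.11). Without myristic acid replicate 1 the cycle had 4 higher and 2 lower entries, and without replicate 2 it had 3 and 2. The median of the cycle was -0.086 without glucose replicate 2, -0.063 with a pseudocount of 10 and -0.31 with a mean FPKM of at least 10.

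Of 13 tested entries for gluconeogenesis and anaplerosis, 4 rose and 3 fell (camera adjusted p = 0.990), or 5 and 3 when adjusted over the list alone, and the median (0.14) and mean (-0.28) of their fold changes differed in sign. The entries that fell were oadA (-2.41 ± 0.17) and accC-2 (-2.25 ± 0.10), which carry the pyruvate carboxylase subunits, and maeB, encoding malic enzyme, from 2939 ± 224 to 920 ± 67.8 FPKM (-1.67 ± 0.10). The entry with the phosphoglycerate kinase gene pgk rose by 0.83 ± 0.12. The 4 higher entries became 2 without glucose replicate 2, glucose replicate 3 or myristic acid replicate 1, and 1 without myristic acid replicate 2. The median of 0.14 became 0.087 without myristic acid replicate 1, and 0.22 without myristic acid replicate 3 and with quantile normalization. The transhydrogenase gene pntB was among the 10 largest rises, from 39.6 ± 6.15 to 1174 ± 53.6 FPKM (4.86 ± 0.13), as was PP_2875, from 169 ± 46.6 to 9626 ± 326 FPKM (5.86 ± 0.19).

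All 8 genes of ATP synthase rose, also when adjusted over the list alone, with log2 fold changes from 0.64 to 1.06. The list was higher by camera (adjusted p = 1.12e-05), with adjusted p = 0.282 at its estimated correlation of 0.65. For example, atpA rose from 3025 ± 295 to 5549 ± 311 FPKM and atpF from 4030 ± 281 to 8412 ± 212 FPKM. In the authors' deposited table atpA, atpB, atpC and atpF had log2 fold changes from 0.71 to 0.85. Their false discovery rates there, from 0.067 to 0.137, were all above 0.05, so the calls rest on limma alone. Without myristic acid replicate 2, 5 of the 8 were called. Of 10 tested entries of NADH dehydrogenase I, the proton-pumping entry point of the respiratory chain, 6 fell and 4 were not called, or 7 and 3 when adjusted over the list alone (median -0.41, camera adjusted p = 0.000621; adjusted p = 0.138 with an estimated correlation). The largest of these falls was that of nuoA, from 376 ± 33.0 to 172 ± 19.0 FPKM (-1.12 ± 0.12), and nuoI fell by 0.88 on the log2 scale with an SE of 0.15. Without myristic acid replicate 3, 3 of the 10 entries were called. In the list of cytochrome o oxidase, cyoE-2 rose by 0.95 ± 0.13 and 3 entries were not called, while 3 rose when adjusted over the list alone (camera adjusted p = 0.0545). Camera called this list without glucose replicate 1 (adjusted p = 0.0478) or 2 (0.0140, with 3 higher entries) and without myristic acid replicate 3 (0.0428).

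**Figure D2:**
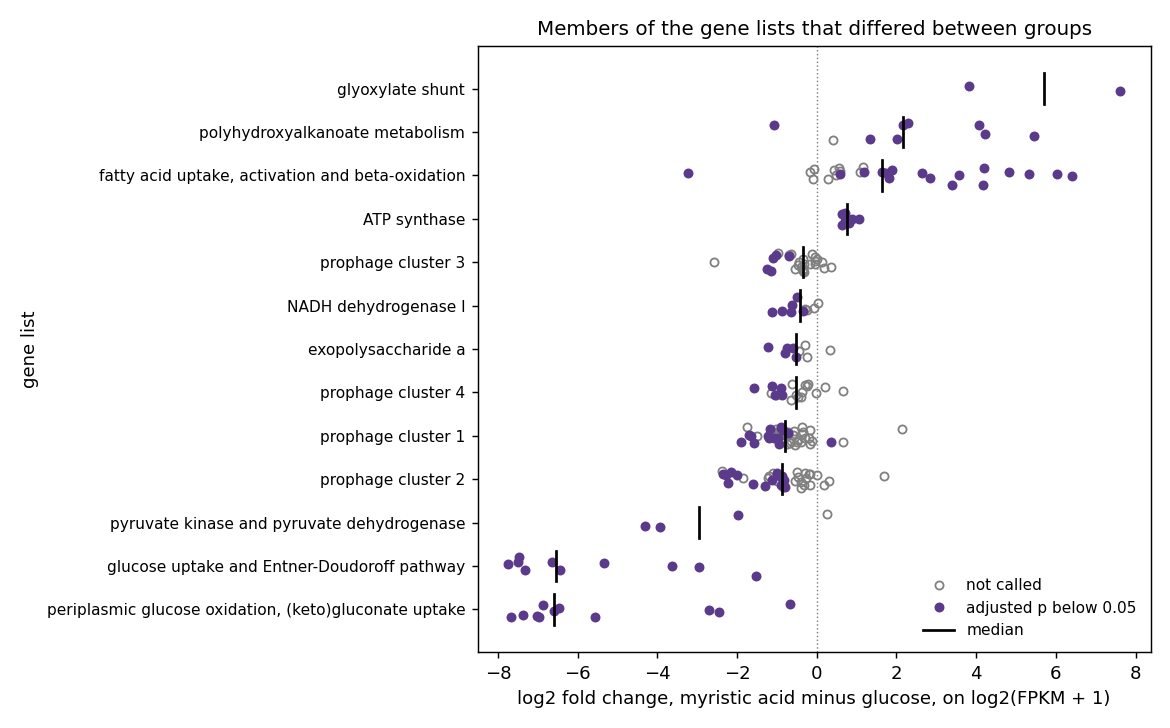
Log2 fold change of each tested entry, myristic acid minus glucose on log2(FPKM + 1), for the 12 lists that camera called at a preset correlation and for the glyoxylate shunt. Filled points are entries with an adjusted p below 0.05, open points entries not called, and the black bar is the list's median, from -6.60 for periplasmic glucose oxidation to 5.71 for the glyoxylate shunt.

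The prophage lists were lower on myristic acid. In prophage cluster 1, 14 of 46 tested entries fell and 1 rose, or 21 and 1 when adjusted over the list alone (median -0.79, camera adjusted p = 1.95e-08; adjusted p = 0.0533 with an estimated correlation). In prophage cluster 2, 14 of 39 fell and none rose, or 18 and 1 when adjusted over the list alone. Its median was -0.88 (camera adjusted p = 1.49e-07), with adjusted p = 0.282 at its estimated correlation of 0.23. In prophage cluster 3, 5 of 27 fell, also when adjusted over the list alone (median -0.35, adjusted p = 0.00369; adjusted p = 0.112 with an estimated correlation). In prophage cluster 4, 5 of 19 fell, or 6 when adjusted over the list alone (median -0.52, adjusted p = 0.00312; adjusted p = 0.112 with an estimated correlation). With a pseudocount of 10 the medians of clusters 1 to 4 were -0.42, -0.53, -0.15 and -0.28, and with a mean FPKM of at least 10 cluster 4 had 3 lower of 9 entries. The entry of PP_3876 to PP_3879 in cluster 1 fell from 71.2 ± 4.07 to 21.9 ± 2.89 FPKM (-1.66 ± 0.14), and PP_1545/PP_1546 in cluster 2 from 100 ± 21.2 to 20 ± 5.04 FPKM (-2.28 ± 0.23). PP_2292 in cluster 3 fell from 181 ± 38.6 to 83.2 ± 12.7 FPKM, and the entry of PP_3037 to PP_3039 in cluster 4 from 175 ± 18.6 to 95.9 ± 13.8 FPKM. The number of lower entries fell to 8 and 6 in cluster 1 without myristic acid replicates 2 and 3, to 9 and 7 in cluster 2 without replicates 1 and 2, and to 3 and 2 in cluster 3 without replicates 2 and 3. In cluster 4 it was 2, 2 and 3 without glucose replicates 1, 2 and 3 and 3, 1 and 1 without myristic acid replicates 1, 2 and 3. The 1 higher entry of cluster 1 was called only without glucose replicate 1, and 1 entry of cluster 2 rose without glucose replicate 3. In each of these fits the set test kept its call.

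Of 9 tested entries of the exopolysaccharide a cluster, 5 fell and 4 were not called, also when adjusted over the list alone (median -0.51, camera adjusted p = 0.0051; adjusted p = 0.175 with an estimated correlation). PP_3134 fell from 84.3 ± 3.89 to 35.4 ± 3.36 FPKM (-1.23 ± 0.12). Without glucose replicates 1, 2 and 3, 3, 1 and 2 of the entries were called, and without myristic acid replicates 1, 2 and 3, 2, 1 and 1. With no filter on low values 3 were called. The flagellar and chemotaxis lists were not called (camera adjusted p = 0.847 and 0.118). The flagellin gene fliC fell from 6993 ± 341 to 4455 ± 288 FPKM. The cap gene fliD fell from 1927 ± 311 to 990 ± 34.5 FPKM and the chemotaxis gene cheV-3 from 353 ± 23.5 to 209 ± 9.74 FPKM. Of 36 flagellar entries, 1 rose and 2 fell, also when adjusted over the list alone. Of 7 chemotaxis entries, 1 fell, or 2 when adjusted over the list alone. The flagellar list had a median of 0.017 and a mean of -0.027, and its 1 higher entry was lost without myristic acid replicate 1 or 3. Without glucose replicate 3, 3 chemotaxis entries fell and camera called that list (adjusted p = 0.0400).

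Among regulators, rpoS, encoding the stationary-phase sigma factor, fell from 1186 ± 163 to 533 ± 72.0 FPKM (-1.15 ± 0.15, adjusted p = 0.0036). The genes of the catabolite repression proteins were not called. These are transcript levels, and the activity of the proteins was not measured. The gene crc had 485 ± 29.4 and 591 ± 10.4 FPKM (0.29 ± 0.09, adjusted p = 0.0597; 0.0490 without glucose replicate 1). PP_4894, listed as hfq, had 3975 ± 1103 and 3381 ± 360 FPKM (adjusted p = 0.483). Of the 8 tested regulators, 2 rose and 1 fell, or 5 and 1 when adjusted over the list alone (camera adjusted p = 0.289). The 2 higher ones became 1 without glucose replicate 2 or without myristic acid replicate 1, 2 or 3. In nitrogen assimilation, 3 of 7 entries rose, also when adjusted over the list alone (camera adjusted p = 0.116), among them ntrB/ntrC, the nitrogen regulators, by 1.54 ± 0.14 and the glutamate dehydrogenase gene gdhA by 0.83 ± 0.13. In fatty acid synthesis, 3 of 14 entries rose and 2 fell, or 4 and 3 when adjusted over the list alone (camera adjusted p = 0.990), with a median of 0.10 and a mean of -0.064, higher by camera and lower by fry. That median was 0.053 without glucose replicate 3, 0.017 without myristic acid replicate 1 and 0.20 without myristic acid replicate 3. The larger fall there was that of PP_4379, listed as fabH, from 182 ± 19.9 to 62.9 ± 9.44 FPKM. Its 3 higher entries became 1 without any 1 of 5 libraries and 0 without myristic acid replicate 2, which also left 1 lower entry.

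Ribosomal protein genes were not called as a list (camera adjusted p = 0.322): 5 of 49 entries rose and none fell, or 4 when adjusted over the list alone. Among them, rplI rose from 2234 ± 480 to 4198 ± 166 FPKM (adjusted p = 0.0107; 0.057 without myristic acid replicate 2). The count of 5 became 2, 3, 2, 0 and 2 without glucose replicates 1 and 3 and without myristic acid replicates 1, 2 and 3, and camera called the list without myristic acid replicate 3 (adjusted p = 0.0248). In the efflux pump list, the entry with mexF and oprN fell by 1.13 on the log2 scale with an SE of 0.16, 1 entry rose and 2 were not called, or 2 and 2 when adjusted over the list alone (camera adjusted p = 0.990). The higher entry was called in only 1 of the 6 leave-one-out fits, without glucose replicate 2. In oxidative stress defence, 1 of 10 entries rose and 3 fell, or 2 and 3 when adjusted over the list alone (camera adjusted p = 0.443). The 3 lower entries became 0 without glucose replicate 1 or 2 and without myristic acid replicate 2 or 3. The 1 higher entry became 2 without glucose replicate 1 and 0 without myristic acid replicate 1, 2 or 3.

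The remaining lists were not called by camera either. Aromatic compound degradation had 1 higher and 2 lower of 15 entries, also when adjusted over the list alone (adjusted p = 0.143). Without glucose replicate 1, 4 of them fell and camera called the list (adjusted p = 0.00514). Only 1 fell without glucose replicate 2 and 0 without glucose replicate 3 or any myristic acid library. In the same list 0 rose without myristic acid replicate 2 or 3. Branched-chain amino acid degradation had 2 lower of 9, or 2 higher and 3 lower when adjusted over the list alone (0.704). Of these, 1 fell without glucose replicate 3 or myristic acid replicate 3, and 0 without any other library. Heat shock and proteases had 1 lower of 14, or 0 when adjusted over the list alone (0.990), with a median of 0.054, lower by camera and higher by fry. In this list 0 fell without glucose replicate 1 or myristic acid replicate 2 or 3, and 1 rose without glucose replicate 2 or myristic acid replicate 1. Pyoverdine and iron uptake had 1 higher of 10 (0.847) and type VI secretion cluster 1 had 1 higher of 10 (0.847), or 1 and 0 when adjusted over the list alone. The pyoverdine count was 0 without glucose replicate 2 and without myristic acid replicates 1 (1 lower) and 2, and the type VI secretion count was 0 without any 1 of the 6 libraries. No entry was called by limma in the lists for alginate (8 tested; adjusted p = 0.289), bacterial cellulose (3; 0.577), the methylcitrate cycle (5; 0.990) and other terminal oxidases (10; 0.325), nor when adjusted over the list alone. At an unadjusted p below 0.05 these lists held 1, 0, 0 and 4 entries. Without glucose replicate 2, 2 other terminal oxidase entries rose, and without glucose replicate 3, 1 did, as did 1 without short, overlapping and RNA entries. The methylcitrate list had a median of -0.0065 and a mean of 0.010. Of the 32 lists tested, camera called 12 at the preset correlation and 0 with an estimated correlation, where 9 had an unadjusted p below 0.05. By fry 18 were called, the 12 among them. Beyond the 12, fry called alginate (adjusted p = 0.0216), chemotaxis (0.0306) and gluconeogenesis and anaplerosis (0.0306) lower. It called nitrogen assimilation (0.00214), regulators (0.000331) and cytochrome o oxidase (0.0306) higher.

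The authors' deposited table holds the authors' own test of the same contrast on the same libraries, so it is not independent of the values above. It lists 600 entries at a false discovery rate below 0.05, 268 with a positive and 332 with a negative log2 fold change, where positive values go with higher FPKM on myristic acid. Of 4394 entries present in the authors' deposited table and in the limma fit, 466 were called in both, all 466 in the same direction, 451 by limma alone and 124 in the authors' deposited table alone. The sign of the fold change differed for 3 of the 451 and for 4 of the 124, the latter all short or RNA entries. For example, RsmY had a log2 fold change of -0.62 ± 0.18 against 1.49 in the authors' deposited table, and tmRNA 0.98 ± 0.31 against -0.88 (both chosen after their values were seen). Entries called by limma alone had a median absolute log2 fold change of 0.64, against 1.19 for those called in both. Across these entries, the log2 fold changes correlated with Pearson's r of 0.892 and Spearman's rho of 0.914. For aceA the log2 fold change in the authors' deposited table was 7.61, for fadB 6.07, for PP_5008 4.94 and for PP_1015 -7.94. With an absolute log2 fold change of at least 1 required in both, 274 calls were shared, with 74 by limma alone and 113 in the authors' deposited table alone.

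**Figure D3:**
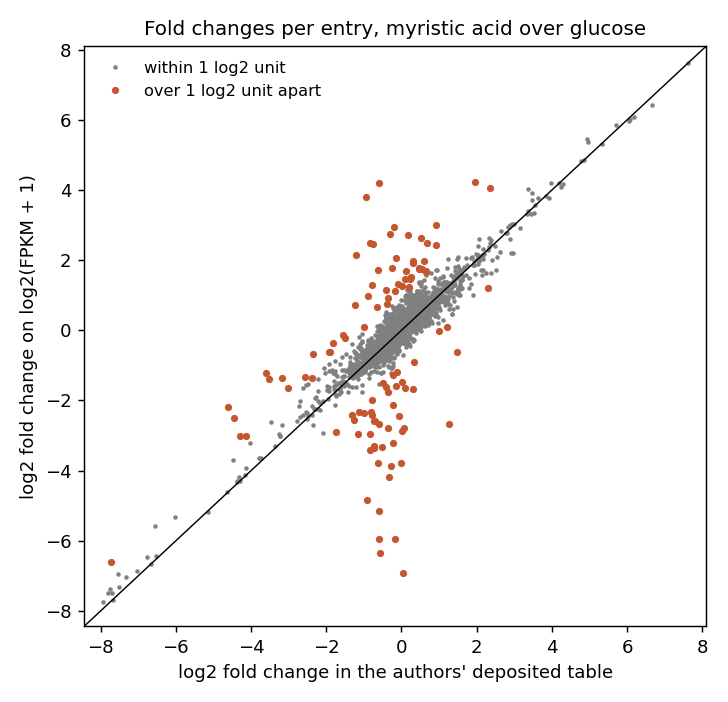
Log2 fold change on log2(FPKM + 1) (vertical axis) against that in the authors' deposited table (horizontal axis), 1 point per entry for 4394 entries, with the line of equal values. Orange points mark the 106 entries whose values differ by more than 1 log2 unit; Pearson's r across entries is 0.892.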

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

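The alternative without short, overlapping and RNA entries was chosen after seeing the data; the other alternatives were planned. Apart from leaving out libraries, the count of 917 called entries ranged from 793 (no trend) to 1019 (replicate block), and 731 to 908 of the 917 were also called, a range that includes fits in which fewer entries were tested. The count of entries at least 1 log2 unit apart fell from 348 to 204 with a pseudocount of 10 (109 higher, 95 lower), which by construction shrinks the fold of low entries. With 1 library left out, 366 to 737 entries were called (207 to 396 higher, 159 to 341 lower), and 241 to 352 at least 1 log2 unit apart (123 to 173 higher, 108 to 179 lower), with fewer samples in each fit. Same-numbered libraries had deviations correlated at -0.029, 0.049 and 0.010, and not every library correlated best with its own number. No pairing was seen in this way, but with 3 libraries per group such correlations cannot exclude a shared day or batch. The replicate block gave 1019 calls, 815 of them among the 917 of the fit without it, and 361 at least 1 log2 unit apart. The 12 lists called by camera stayed called at the preset correlation in each of the other fits, and 12 to 14 lists were called in them; the robust fit has no list result because camera has no such option. Whether a list changed direction was judged by the sign of its median, a choice made after camera's own direction had been seen; camera's direction changed for 8 of 32 lists, 0 of them called. With an estimated correlation 0 of 32 lists were called by camera, 9 at an unadjusted p below 0.05, and the lowest adjusted p was 0.0533. That test has 4 degrees of freedom, which raises p. Among called lists the estimate was below 0.01 for polyhydroxyalkanoates (0.0014), pyruvate kinase and dehydrogenase (-0.074), prophage cluster 3 (0.0057) and cluster 4 (-0.026). It was above 0.01 for the other called lists, up to 0.65 for ATP synthase. Below 0.01 a larger correlation does not account for the rise. By fry, which asks only whether a list's genes move one way, 18 were called, the 12 among them. The calls shared with the authors' table went from 466 to 274 when a log2 fold change of at least 1 was required. The median of lists that were not called changed sign in these fits: efflux pumps with a pseudocount of 10 (0.063) and with a mean FPKM of at least 10 (0.35), branched-chain amino acid degradation with a mean FPKM of at least 10 (0.28), flagellar motility with median-of-ratios (-0.017) and quantile scaling (-0.0027), and the methylcitrate cycle with quantile normalization (0.017). With 1 library left out, the median of lists not called spanned 0 in branched-chain amino acid degradation (-0.119 to 0.108), flagellar motility (-0.108 to 0.0789), heat shock (-0.129 to 0.143), the methylcitrate cycle (-0.00749 to 0.0657), pyoverdine (-0.00826 to 0.123) and ribosomal proteins (-0.00233 to 0.13). Of 106 named entries called, 93 kept direction and call in each fit that used all libraries, 72 in each fit that left one out, and none changed sign. Named entries that were not called changed sign: PP_2333/PP_2334 with quantile normalization (0.017), PP_2637/PP_2638 with a pseudocount of 10 (-0.021) and median-of-ratios scaling (-0.013), and ccoP-2/ccoQ-2 with both scalings (-0.025 and -0.027). With 1 library left out, such entries spanned 0: PP_2333/PP_2334 (-0.153 to 0.0829), PP_2337 (-0.0435 to 0.177), prpD (-0.0773 to 0.0256), PP_2637/PP_2638 (-0.433 to 0.362), PP_1893 (-0.214 to 0.107), PP_4894 (-0.346 to 0.0119), mgtC (-0.17 to 0.543), arcA (-0.204 to 0.666) and ccoP-2/ccoQ-2 (-0.199 to 0.140). Nitrogen assimilation was called with quantile normalization (adjusted p = 0.0422) and cytochrome o oxidase with a replicate block (0.0180). With the replicate block the called entries of some lists also moved: exopolysaccharide a from 5 to 2 lower, heat shock from 0 higher and 1 lower to 3 and 3, other terminal oxidases from 0 to 2 higher, cytochrome o oxidase from 1 to 3 higher, branched-chain amino acid degradation from 2 to 1 lower, chemotaxis from 1 to 2 lower, regulators from 2 to 1 higher, prophage cluster 2 from 0 to 1 higher and type VI secretion from 1 to 0 higher. With no filter on low values, oxidative stress went from 3 to 1 lower and regulators from 2 to 4 higher. DESeq2 and other count models were not run, because no counts were found.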

Other observations

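The genes named here and the tests on them were chosen after the values were seen, except the comparison with other splits of the libraries. Besides the fatty acid genes, the genes for glycerol uptake and phosphorylation, glpF and glpK, rose. The glycerol channel gene glpF went from 27.0 ± 0.596 to 237 ± 72.2 FPKM (SD, n = 3, log2 fold change 3.04 ± 0.23 SE, limma adjusted p = 0.000235). The glycerol kinase gene glpK went from 44.3 ± 0.142 to 312 ± 72.5 FPKM (2.76 ± 0.18). Their neighbour glpR, a repressor gene, had 60.5 ± 4.08 and 80.7 ± 6.31 FPKM and an adjusted p of 0.0470, which lay between 0.0661 and 0.124 with any 1 library left out. The neighbouring entries PP_3923 (4.04 ± 0.15), PP_3924 (3.77 ± 0.13), PP_3925 (3.71 ± 0.10) and PP_3926 (3.32 ± 0.16) also rose, with PP_3924 going from 626 ± 74.1 to 8557 ± 812 FPKM.

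A run of neighbouring entries from PP_3781 to dapF-1 (4308593 to 4319834) fell. PP_3781 went from 3731 ± 1260 to 190 ± 80.8 FPKM (-4.32 ± 0.34, adjusted p = 0.000281), PP_3785 from 3235 ± 1317 to 162 ± 52.4 FPKM (-4.28 ± 0.32) and dapF-1, named for a diaminopimelate epimerase, from 806 ± 370 to 93.6 ± 13.3 FPKM (-3.01 ± 0.30). The aerotaxis receptor gene aer-1 fell from 37.2 ± 5.72 to 6.0 ± 1.82 FPKM and its neighbour PP_2258 from 53.1 ± 4.04 to 8.02 ± 1.47 FPKM, while aer-2 had 43.2 ± 7.28 and 37.1 ± 8.73 FPKM (adjusted p = 0.470).

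These tests were chosen after the result was seen. The outer membrane protein gene oprH rose from 274 ± 68.1 to 3733 ± 623 FPKM (3.78 ± 0.22) and the entry of the 2-component genes phoP and phoQ from 76.1 ± 14.6 to 778 ± 199 FPKM (3.32 ± 0.22). This system answers to low magnesium in other pseudomonads, and fatty acids bind divalent cations, so scarce cations might be a cause. The magnesium transport genes mgtB, mgtC and mgtE had a median log2 fold change of 0.22, with 0 called and a largest SE of 0.47. On glucose and myristic acid, mgtB had 2.64 and 1.49 FPKM and mgtC 2.26 and 2.74 FPKM, values that rest on few fragments. The change was -0.56 ± 0.28 for mgtB, 0.22 ± 0.47 for mgtC and 0.32 ± 0.13 for mgtE. This leaves the question of scarce cations open. Under other scalings of the libraries the smaller of the changes of oprH and of the phoP and phoQ entry was 3.29. Those scalings moved the median log2 fold change of all entries only from 0.024 to -0.0080 (median-of-ratios) and 0.031 (quantile). The choice among these scalings therefore does not account for the rise, but a change of this size was out of their reach from the start.

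These tests were chosen after the result was seen. The entries oprG and PhrS, each sharing its span with another entry, were lower in glucose replicate 3 than in the other glucose libraries; their calls (2.06 ± 0.54 and 2.61 ± 0.64) held only without glucose replicate 1 or 3. Less oxygen in glucose replicates 1 and 2 might be a cause. However, 6 entries taken as linked to oxygen differed in replicate 3 by a median of -0.62 log2 units, from -1.57 to 0.23. Which of the 6 respond to oxygen in this strain was not tested. Of 1929 long single entries, 0.726% (14) were at least 1 log2 unit lower in replicate 3; this alone would have met the condition written for a poor estimate of short or overlapping entries. Because arcD and hemN, long entries linked to oxygen, were among the 14, that test was set to undecided after its value was seen. The terminal oxidase entry ccoN-1, not one of the 6, was also among the 14. In replicate 3 it stood at -1.76 log2 units, against -1.57 for arcD and -1.37 for hemN. The largest drop among the 14 was that of ssuE (-1.78), and cysP (-1.39) was also there, so the 14 do not single out oxygen. Such counts were 3 and 7 for glucose replicates 1 and 2 and 4, 13 and 1 for myristic acid replicates 1 to 3. Of the 6, the ccoN-2/ccoO-2 and ccoP-2/ccoQ-2 entries stood at 0.23 and 0.22.

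These tests were chosen after the result was seen. Between the fold changes from FPKM and those in the authors' deposited table, 106 of the entries in both differed by more than 1 log2 unit. Short entries or entries that share their span made up 60.4% of them and 7.25% of the other 4288, a ratio of 8.32 (Fisher p = 6.03e-43), so such entries are a likely source. Entries that share a span are not independent of each other, so this p-value is likely too small. Entries with a mean FPKM under 10 made up 32.1% of the 106 and 24.7% of the others, so low values alone do not account for it. Of the 106, 12 were called by limma.

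The tests of other splits were fixed before the result was seen. Of the 10 splits of the libraries into 3 and 3, only 1, the real one, gave 917 calls, and the highest other gave 3. With an absolute log2 fold change of at least 1 the real split gave 348 and the highest other 3. With 10 splits no share under 0.05 can be reached. Every other split mixes both carbon sources within each group, so the difference between them counts as spread there. Few calls were therefore likely in those splits from the start, and the contrast with 917 says little about chance.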
